A study of Mus musculus with 30 samples.

How the data were processed

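RNA from testis, liver, skeletal muscle, brain and heart of mice lacking Clpp and of wild-type littermates on a C57BL/6 background was measured on 30 Affymetrix mouse expression arrays, with 3 arrays for each of the 10 combinations of tissue and genotype. The authors processed the arrays with RMA in R 2.14.0, and the deposited values are log2 expression values per probe set, normalized between arrays by the authors. The files do not state whether all 30 arrays went through RMA together. No further normalization was applied here. Array medians lay between 3.24 and 3.38, and the number of arrays limits the precision of every comparison.

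The table held 45141 probe sets. Of these, 28898 were assigned to exactly 1 gene symbol, 551 to several symbols and 15692 to no gene, the last including 104 control probe sets. A gene was represented by the probe set with the highest mean over the 30 arrays among those assigned to that symbol alone, which gave 17097 genes, 7180 of them with more than 1 such probe set. Gene names came from the probe table supplied with the series, and 16937 of the genes were found by Entrez identifier in a table of the GRCm38.p6 assembly, which served for names and for the neighbours of Clpp and for no printed coordinate. The 15588 probe sets with no gene, controls left out, were tested separately.

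All genes were fitted with limma 3.58.1 in R 4.3.3 in a single fit of the 10 group means with 20 residual degrees of freedom and the default empirical Bayes prior. Contrasts were knockout minus wild type in each tissue, their mean over the 5 tissues, and each tissue against the mean of the other 4. A moderated F test of the 4 independent differences between tissues tested whether the knockout effect differed between tissues. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p below 0.05 within each contrast. Errors of log2 changes are standard errors from this fit, with 3 arrays per group, and adjusted p values are from limma. The fit pools the spread of each gene over all 10 groups, so an SE can be too small for a group that varied more than the others. The labels do not say that replicates are separate animals, so a p value here measures the spread between these samples. They also do not say whether the same animals gave all 5 tissues, so the 15 arrays of a genotype may come from as few as 3 animals, and the fit treats them as independent.

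The gene lists, the rule for named genes and the alternatives, except where said, were fixed before the data were examined. Of 63 lists of pathways, complexes, cell types and sex 62 had at least 3 measured members. They were tested with camera at a preset correlation of 0.01 on the moderated statistics, adjusted over 372 tests of list by contrast. List tests of 1 tissue against the mean of the other 4 were adjusted as a separate family of every list in every tissue. Camera with an estimated correlation and fry were run beside it. Of the 372 tests 74 were called, 13 of them also with the estimated correlation, and fry called 83. Fry asks whether the genes of a list move on balance one way and compares them with no other genes. Genes on chromosome 17 within 10 Mb of Clpp were compared with all other genes by Fisher's exact test.

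Named genes followed a rule. For each tissue these were the 10 largest rises and 10 largest falls among called genes whose 3 knockout arrays all lay on one side of the 3 wild-type arrays and whose mean log2 level was at least 6 in either genotype. Chance alone gives such a separation of 3 against 3 arrays for 10% of genes. For the mean over tissues these were the 15 largest rises and falls among called genes with 1 sign in all 5 tissues, for the difference between tissues the 5 genes with the smallest p, and for each discussed list up to 4 called members. A change of a named gene of a tissue was read as a lower bound where the lower group mean was under 4, a limit chosen after the values were seen. Clone names and predicted genes were left out and counted for the tissues and for the mean over tissues, and were not left out for the difference between tissues. No named gene had another probe set of opposite sign at an unadjusted p below 0.05.

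The alternatives tried were a fit of each tissue alone, a replicate block, animals as a random block across tissues, a trended robust prior, array weights, quantile normalization and median centring of the deposited values, filters on dim genes, other rules for probe sets, and each array left out in turn. List tests, the window around Clpp, the tissues in the mean and the threshold of the overlap were also varied. Leaving out a pair of arrays that stood apart, and testing 4 tissues without testis, were added after the data had been seen. Replicate numbers did not pair knockout with wild-type arrays in any tissue by the correlation of their deviations, which had to exceed 0.1 for every same-numbered pair.

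The fit was tested on simulated data of the same size with 200 changed genes per comparison. In the tissue comparisons it recovered 25.4% of genes changed by 0.5 in liver and 32.8% in testis, with the other tissues in between. Of genes changed by 1 it recovered between 82.1% in liver and muscle and 94% in testis, and of genes changed by 2 between 97% in heart and 100% in liver and brain. False calls numbered between 5 and 14 of 16897 unchanged genes per tissue. The simulated noise was independent and normal with a single spread per gene, without arrays that stand apart or animals shared between tissues. These rates may therefore not hold for the real arrays.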

Results

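The series compared mice lacking ClpP, the proteolytic subunit of a protease in the mitochondrial matrix, with wild-type littermates in 5 tissues in a factorial design. Transcript levels were measured as log2 expression on 30 arrays, 15 from knockout and 15 from wild-type mice, with 3 arrays per genotype in testis, liver, skeletal muscle, brain and heart. Values ranged from 1.73 to 14.1, array medians from 3.24 to 3.38, and 5168 of 17097 genes had a mean of at least 6. The 3 arrays per group limited the precision.

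The targeted gene itself was measured first. Clpp signal was lower on every knockout array than on every wild-type array. The highest knockout value was 3.99, the lowest wild-type value was 5.88 in testis, and outside testis the lowest wild-type value was 7.79. Clpp fell by 5.56 ± 0.19 on the log2 scale in heart (SE, n = 3 per genotype), where the wild-type mean was 9.18 ± 0.04 (SD). It changed by -5.39 ± 0.19 in liver, -4.86 ± 0.19 in brain, -4.82 ± 0.19 in muscle and -3.23 ± 0.19 in testis, where the wild-type mean was 6.38 ± 0.53 (SD). Knockout means lay between 3.11 and 3.65, near the array medians of 3.24 to 3.38, so the differences are lower bounds that follow the wild-type level of each tissue. A second Clpp probe set changed by -5.56, -5.48, -4.93, -4.92 and -3.12 in the same order of tissues. Clpx, the partner ATPase of ClpP, had no probe set in the gene table and was not analysed here.

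**Figure D1:**
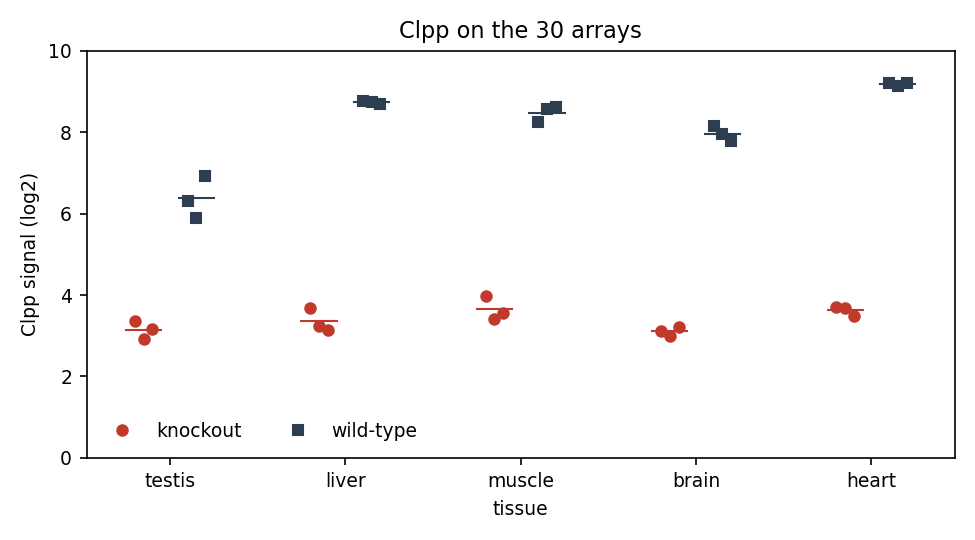
Clpp signal (log2) on each of the 30 arrays by tissue, with knockout arrays as circles, wild-type arrays as squares and a line at each group mean of 3 arrays. The highest knockout value is 3.99 and the lowest wild-type value is 5.88.

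In testis Tssk6, a kinase of spermatids, fell by 6.12 ± 0.22 on the log2 scale (SE, n = 3 per genotype). Spem1, needed for sperm maturation, fell by 5.71 ± 0.23, H2al2a, a histone variant of the testis, by 5.63 ± 0.23, Oxct2a, a ketone body enzyme of germ cells, by 5.57 ± 0.20, and Spata3 by 5.52 ± 0.22. Nudt16l2, Ubqlnl, Tex35, Pdzk1 and Kctd16 changed by between -5.79 and -5.54. Mars1, the cytosolic methionyl-tRNA synthetase, rose by 3.07 ± 0.12 and Timp1, an inhibitor of matrix metalloproteinases, by 3.06 ± 0.24. Igfbp3, which binds insulin-like growth factors, rose by 2.95, Shbg, which binds sex steroids, by 2.90, Apoc1, an apolipoprotein, by 2.81, and Mpeg1, a macrophage gene, by 2.80. Scara3, Tspan8, Cytip and Prkd1 rose by between 2.78 and 2.99. The lower group mean was under 4, near the array medians, for Timp1, Scara3, Igfbp3, Tspan8, Shbg, Nudt16l2, Ubqlnl, Tex35 and Pdzk1, so their changes are read as lower bounds with no exact order. In all 9605 of 17097 genes (56.2%) were called, of which 5608 rose and 3997 fell, and 2906 rises and 2260 falls were at least 1 on the log2 scale. The eligible genes also held 72 rises and 282 falls with clone names. The median change was 0.02 over all genes and 0.69 over the 5168 genes with a mean of at least 6. With genes limited to those above the median of overall means, 6393 of 8548 were called.

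Of the testis cell lists, those of spermatids fell and those of Sertoli, Leydig and spermatogonial cells rose. Of 22 genes of elongating spermatids and sperm, 21 fell, also when adjusted over the list alone, and 1 was not called (median -4.22; adjusted p = 6.69e-12, but adjusted p = 0.292 with an estimated correlation). Besides Tssk6, Spem1 and Spata3, these included Fscn3, an actin-bundling protein of spermatids, which fell by 5.40 ± 0.13. Of 19 round spermatid genes 18 fell, with 18 adjusted over the list alone (median -3.14; adjusted p = 1.63e-11, and adjusted p = 0.292 with an estimated correlation). Among them Actl7a changed by -4.86 ± 0.25, the sperm calcium channel subunit Catsper3 by -4.67 ± 0.17 and the kinase Tssk2 by -4.53 ± 0.29. All 17 Sertoli cell markers rose, again 17 adjusted over the list alone (median 1.81; adjusted p = 8.69e-07, and adjusted p = 0.00388 with an estimated correlation), led by the transcription factor Sox8 at 2.40 ± 0.16 and the inhibin subunit Inha at 2.34 ± 0.23. Of 12 Leydig cell markers 11 rose and 1 fell, with the same counts adjusted over the list alone (median 1.52; adjusted p = 0.00144, and adjusted p = 0.0788 with an estimated correlation), and the steroid enzymes Hsd3b1 and Hsd17b3 rose by 2.19 ± 0.11 and 2.13 ± 0.12. Of 14 spermatogonial markers 10 rose, 11 adjusted over the list alone (median 1.28; adjusted p = 0.0161, and adjusted p = 0.0821 with an estimated correlation), including Dmrt1 at 2.02 ± 0.18, Dazl at 1.98 ± 0.15 and Kit at 1.89 ± 0.18. The 22 meiotic spermatocyte genes were split, with 10 up and 6 down under either adjustment, a median of 0.22, a mean of opposite sign at -0.11 and an adjusted p of 0.642. There the glycolytic enzyme Pgk2 fell by 4.08 ± 0.37 and the meiotic gene Meiob rose by 1.84 ± 0.27. The endothelial list had a median of 0.16 and a test direction of down (adjusted p = 0.966), the fibroblast list 0.08 (adjusted p = 0.607) and the smooth muscle and myoid list 0.08 with a mean of -0.01 (adjusted p = 0.99).

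**Figure D2:**
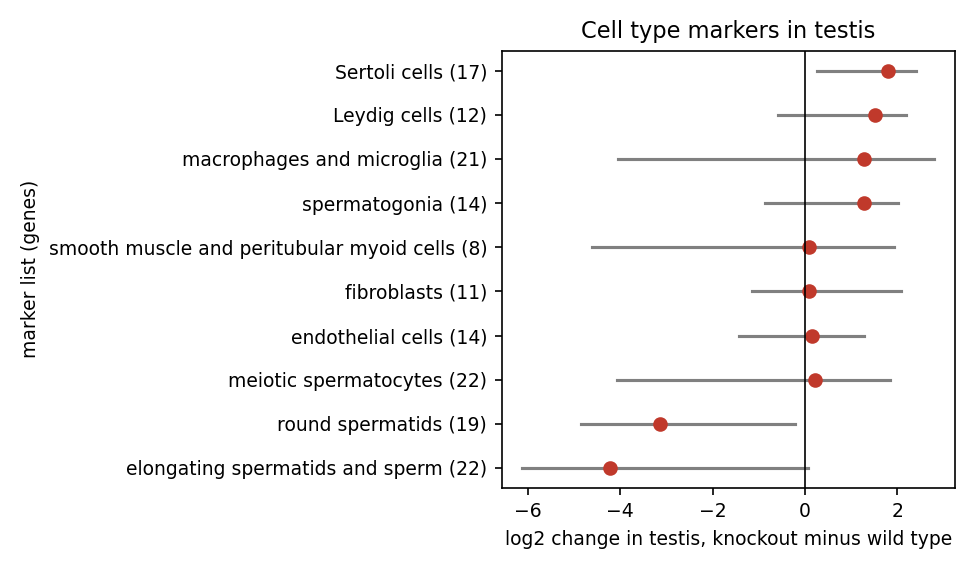
Log2 change in testis (knockout minus wild type, n = 3 arrays per genotype) for marker lists of cell types, with the number of measured genes in brackets. Points are list medians and lines run from the lowest to the highest member; the median is -4.22 for elongating spermatids and sperm and 1.81 for Sertoli cells.

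Further lists passed in testis. Camera compares a list with all 17097 genes, whose median change was 0.02. Over the 5168 genes with a mean of at least 6 the median change was 0.69. The medians below of 0.75, 0.40 and 0.54 lie near or under it, so those calls do not set the lists apart from other genes of higher signal. Of 70 cytosolic ribosomal protein genes 61 rose and 1 fell, with 61 and 2 adjusted over the list alone (median 0.75; adjusted p = 2.72e-10, but adjusted p = 0.642 with an estimated correlation), among them Rps4x and Rpl36a, each up by 1.64. Of 78 nuclear genes of oxidative phosphorylation 45 rose and 5 fell under either adjustment (median 0.40; adjusted p = 0.000868, and adjusted p = 0.792 with an estimated correlation), such as Cox7a1 at 1.97 ± 0.20. Of 73 mitochondrial ribosomal protein genes 40 rose and 7 fell under either adjustment (median 0.54; adjusted p = 0.0122, and adjusted p = 0.808 with an estimated correlation), with Mrpl58 up by 1.53 and Mrps36, also known as a subunit of the oxoglutarate dehydrogenase complex, at a change of -2.03. Of 28 genes of fatty acid oxidation 14 rose and 2 fell under either adjustment (adjusted p = 0.0208, and adjusted p = 0.843 with an estimated correlation), led by Hadh at 2.04 ± 0.15. Of 21 markers on the list of macrophages and microglia 16 rose and 1 fell under either adjustment (median 1.28; adjusted p = 0.0305, and adjusted p = 0.837 with an estimated correlation). The fall there was Aif1 at -4.05 ± 0.23, and the call was lost without knockout replicate 1 (adjusted p = 0.0637). Of 21 interferon-gamma and GTPase genes 15 rose and 2 fell under either adjustment (median 1.14; adjusted p = 0.0454, and adjusted p = 0.808 with an estimated correlation), with the GTPases Tgtp1 at 2.37 ± 0.29 and Iigp1 at 2.27 ± 0.33. That call was lost without any of 8 single arrays, namely each testis array but knockout replicate 3, liver knockout replicate 3, brain wild-type replicate 3 and heart knockout replicate 3, with adjusted p between 0.05 and 0.0848. The type I interferon list held 17 rises and 3 falls among 36 genes under either adjustment and did not pass (adjusted p = 0.174). Its RNA sensor Dhx58 fell by 2.03 ± 0.17 while Ifi27 and Xaf1 rose by 1.82 and 1.79. The 3'-minus-5' difference of the GAPDH control probe sets was 0.55 ± 0.04 on knockout and 0.98 ± 0.17 on wild-type testis arrays (SD, n = 3), and that of the actin control was 1.23 ± 0.08 and 1.66 ± 0.33. On wild-type replicate 3 the epididymal genes Lcn5, Lcn8 and Adam7 stood at 11.7, 10.5 and 10.7, against means of 2.68, 2.63 and 3.01 on the other 5 testis arrays. The 4 epididymal markers were called lower in knockout, and without that array only Adam7 was (-0.51, adjusted p = 0.00101), with Lcn5 at adjusted p = 0.0511.

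In liver Cyp2b9 and Cyp2b13, female-predominant cytochromes P450, rose by 3.70 ± 0.59 and 2.87 ± 0.33 on the log2 scale (SE, n = 3 per genotype). Etnppl, which breaks down phosphoethanolamine, rose by 2.80 ± 0.45, the antiviral genes Oas1g and Usp18 by 2.25 ± 0.17 and 2.03 ± 0.19, and Ndrg1, a stress-responsive gene, by 2.02 ± 0.22. Acot3, a peroxisomal thioesterase, Cyp17a1, a steroid hydroxylase, Hamp2, a hepcidin paralog, and the glutathione transferase Gstm3 rose by between 1.85 and 1.95. Besides Clpp, there were changes of -3.31 ± 0.19 in the adipokine Serpina12, -2.98 ± 0.34 in the organic anion transporter Slc22a7, -2.89 ± 0.34 in the male-predominant steroid enzyme Hsd3b5 and -2.78 ± 0.53 in the acute phase protein Saa2. Cav1, Gpc1, Gnai1, Sult5a1 and Ppp1r9a changed by between -2.59 and -2.12. With a lower group mean under 4, the changes of Cyp2b13, Etnppl, Cav1, Gpc1, Gnai1 and Ppp1r9a are read as lower bounds. Wild-type SDs were 2.36 for Cyp2b9, 2.08 for Saa2, 1.55 for Acot3, 1.43 for Cyp17a1, 1.36 for Slc22a7 and 1.07 for Sult5a1. Knockout SDs were 1.78 for Etnppl, 1.2 for Cyp2b13 and 1.09 for Hsd3b5. The pooled SEs of these genes understate the spread of those liver arrays. The 3'-minus-5' difference of the actin control was 2.08 ± 0.30 on knockout and 1.71 ± 0.06 on wild-type liver arrays (SD, n = 3), and knockout replicate 1 had the highest actin and GAPDH differences of all 30 arrays at 2.39 and 1.66. In all 413 genes were called, 156 up and 257 down, with 59 rises and 80 falls of at least 1, besides 2 eligible rises and 6 eligible falls with clone names. Hamp2 turned to -0.10 with a probe set not shared between genes, and Acot3 lost its call without knockout replicate 1 (adjusted p = 0.0569). Fitted on its own 6 arrays, liver gave 31 genes, among them 8 of the 20 named.

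Of 36 type I interferon-stimulated genes in liver 15 rose, 24 adjusted over the list alone, and none fell (median 0.65; adjusted p = 9.9e-28, and adjusted p = 0.000582 with an estimated correlation). Besides Usp18 these included Ifit1 at 1.83 ± 0.19, Rsad2 at 1.43 ± 0.16 and the regulator Irf7 at 1.36 ± 0.20. Of 21 interferon-gamma and GTPase genes 3 rose, 6 adjusted over the list alone (median 0.33; adjusted p = 1.78e-07, but adjusted p = 0.241 with an estimated correlation). These were Igtp at 1.29 ± 0.32, Gbp3 at 1.23 ± 0.22 and Tapbp at 0.74 ± 0.15, and Igtp lost its call without any liver array but wild-type replicate 1 (adjusted p between 0.0511 and 0.105). Of 26 xenobiotic-metabolising genes 8 rose and 1 fell, with 16 and 1 adjusted over the list alone (median 0.49; adjusted p = 3.08e-09, and adjusted p = 0.0325 with an estimated correlation). With Cyp2b9, Cyp2b13 and Gstm3, Gsta2 rose by 1.57 ± 0.34, a call lost without wild-type replicate 3 (adjusted p = 0.071), and the fall was the male-predominant Cyp2d9 at -1.05 ± 0.12. Of 20 hepatic sex-biased and growth hormone-regulated genes 3 rose and 6 fell, with 5 and 8 adjusted over the list alone (median -0.28; adjusted p = 0.00402, but adjusted p = 0.0788 with an estimated correlation). Here Elovl3, which elongates fatty acids, fell by 2.10 ± 0.18, and the list call was lost without knockout replicate 3 (adjusted p = 0.0576). Of 23 acute phase genes 1 rose and 4 fell, 1 and 6 adjusted over the list alone (median -0.26; adjusted p = 0.00637, but adjusted p = 0.641 with an estimated correlation). Without wild-type replicate 3, on which the list's median stood 0.40 above the wild-type mean, that call was lost (adjusted p = 0.395). Of 73 mitochondrial ribosomal protein genes only Mrps18a was called, under either adjustment, at a change of -0.61 (list median -0.135; adjusted p = 4.08e-06, but adjusted p = 0.624 with an estimated correlation).

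In skeletal muscle the slow-fibre contractile genes rose. Tnnc1, Tnni1 and Tnnt1, the slow troponins, rose by 4.74 ± 0.52, 4.70 ± 0.44 and 4.05 ± 0.56 on the log2 scale (SE, n = 3 per genotype), and the slow myosin heavy chain Myh7 by 4.52 ± 0.48. Their wild-type SDs in muscle were 2.1, 1.57, 1.85 and 1.86 in that order, so the pooled SEs understate the spread of the wild-type muscle arrays. The light chain Myl2 rose by 3.19 ± 0.59, cardiac actin Actc1 by 2.83 ± 0.27, the calcium pump Atp2a2 by 2.32 ± 0.29 and Myom3, of the sarcomere M-band, by 2.31 ± 0.35. Wild-type SDs were 2.45 for Myl2, 0.92 for Actc1, 1.14 for Atp2a2 and 1.19 for Myom3, so the same limit holds for their SEs. Plet1os and the growth factor-binding Fgfbp1 rose by 2.20 ± 0.22 and 2.12 ± 0.17. Besides Clpp, the haptoglobin gene Hp changed by -2.49 ± 0.61, the transcription factor Klf10 fell by 2.21 ± 0.36 and the survival factor Bcl2 fell by 1.90 ± 0.19. The knockout SD of Hp was 1.17, so its pooled SE understates the spread of the knockout muscle arrays. Aplnr, the apelin receptor, Il1r1, an interleukin receptor, Eda2r, Rai14, Tmem37 and Mgst1 changed by between -1.54 and -0.93. In all 263 genes were called, 133 up and 130 down, with 51 rises and 21 falls of at least 1, while 178 rose and 76 fell after a second quantile normalization and 118 rose and 151 fell after median centring. The eligible genes also held 1 rise with a clone name. Of 13 slow and oxidative fibre genes 9 rose, 12 adjusted over the list alone, and none fell (median 1.81; adjusted p = 1.22e-27, and adjusted p = 1.3e-05 with an estimated correlation). The median stood between 1.58 and 1.99 above the wild-type mean on the 3 knockout arrays and between -0.59 and 0.43 on the 3 wild-type arrays. The fast and glycolytic list (15 genes, none called under either adjustment in limma) had a median of 0.01, a mean of -0.03 and an adjusted p of 0.82. Of 14 cardiomyocyte markers 4 rose, 5 adjusted over the list alone (median 0.17; adjusted p = 5.59e-07, and adjusted p = 0.00071 with an estimated correlation), and these, Myl2, Actc1, Myl3 and Myoz2, are also genes of slow fibres or of muscle development.

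Interferon-stimulated genes rose in muscle too. Of 36 type I genes 16 rose, 19 adjusted over the list alone, and none fell (median 0.40; adjusted p = 4.36e-23, and adjusted p = 0.00131 with an estimated correlation), with Ifit1 at 2.23 ± 0.19, Ifit3 at 1.96 ± 0.23 and Usp18 at 1.88 ± 0.19. Of 21 interferon-gamma and GTPase genes 4 rose, with 12 up and 1 down adjusted over the list alone (median 0.71; adjusted p = 1.05e-11, but adjusted p = 0.0788 with an estimated correlation). Of these 4 genes Ifi47, a GTPase, rose by 1.59 ± 0.30, and Tgtp1, Gbp3 and Gbp2 changed by 1.19, 1.02 and 0.75. Sperm transcripts were found on muscle wild-type replicate 1, where 22 sperm genes had a median of 4.83 and the protamine Prm1 stood at 8.11. The median was between 2.92 and 3.09 on the other 5 muscle arrays and 11.5 in wild-type testis. The list of elongating spermatids and sperm, with none of 22 genes called under either adjustment, passed as lower in knockout muscle (adjusted p = 0.00637, adjusted p = 0.824 with an estimated correlation) and lost its call without that array (adjusted p = 0.47). Without it 156 genes were called, 91 up and 65 down, of which 123 were among the 263. Without wild-type replicate 3 there were 141, and without knockout replicates 1, 2 and 3 there were 125, 165 and 142. Fitted alone, muscle gave 15 genes, 3 of the 20 named among them (Clpp, Klf10 and Bcl2), and with every probe set tested 435.

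Calls of 6 named muscle falls and of 3 GTPases were lost with 1 array left out. Mgst1 lost its call without any of the 6 arrays (adjusted p between 0.0552 and 0.115) and Hp without any but knockout replicate 3 (0.0675 to 0.187). Tmem37 lost it without any knockout array or wild-type replicate 1 (0.0535 to 0.146), Rai14 without knockout replicates 1 or 3 or wild-type replicate 1 (0.0767 to 0.117). Il1r1 lost it without knockout replicates 1 or 3 or wild-type replicate 3 (0.0606 to 0.128), Aplnr without knockout replicates 1 or 2 or wild-type replicate 2 (0.0519 to 0.0794). Among the GTPases, Gbp2 lost its call without any array but knockout replicate 2 (0.081 to 0.23), Gbp3 without knockout replicates 1 or 3 or wild-type replicates 1 or 2 (0.0521 to 0.0942), and Tgtp1 without knockout replicates 1 or 3 or wild-type replicate 3 (0.0671 to 0.19).

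In brain Ifi27l2a, an interferon-stimulated gene, rose by 3.34 ± 0.52 on the log2 scale (SE, n = 3 per genotype), Ifit3, an antiviral RNA-binding protein, by 2.46 ± 0.23, Rtp4 by 2.39 ± 0.19 and the GTPase Tgtp1 by 2.38 ± 0.29. Lgals3bp rose by 1.94 ± 0.24, the guanylate-binding protein Gbp10 by 1.77 ± 0.25, Ifi27 by 1.55 ± 0.12, the antiviral membrane protein Ifitm3 by 1.47 ± 0.29, the class I antigen H2-K1 by 1.42 ± 0.19 and the GTPase Irgm1 by 1.26 ± 0.23. The wild-type mean of Ifi27l2a was 3.02, below the array medians, so its rise is read as a lower bound. Besides Clpp, 5 genes met the rule among the falls. Ttll1, a tubulin polyglutamylase subunit, changed by -1.34 ± 0.27, Spag7 by -0.96 ± 0.15, Nkain2 by -0.93 ± 0.21, Tbc1d24 by -0.92 ± 0.20 and Srek1, a splicing protein, by -0.53 ± 0.10. In all 71 genes were called, 40 up and 31 down, with 30 rises and 9 falls of at least 1, with 47 up and 19 down after a second quantile normalization and 40 up and 26 down after median centring. Of 36 type I interferon-stimulated genes 15 rose, 24 adjusted over the list alone, and none fell (median 0.65; adjusted p = 1.04e-54, and adjusted p = 7.76e-06 with an estimated correlation), among them Ifit1 at 2.73 ± 0.19. Of 21 interferon-gamma and GTPase genes 8 rose, 12 adjusted over the list alone (median 0.71; adjusted p = 5.83e-19, and adjusted p = 0.011 with an estimated correlation), with Iigp1 at 1.98 ± 0.33 after Tgtp1. The microglial list passed with no member called under either adjustment (median 0.30; adjusted p = 0.000868, but adjusted p = 0.731 with an estimated correlation) and lost its call without wild-type replicate 1 (adjusted p = 0.126).

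Brain wild-type replicate 3 stood apart from the other 5 brain arrays. The first principal component of the brain arrays held 68.1% of the variance, with that array at 32.8 and the others between -8.70 and -4.82. The growth hormone gene Gh stood at 11.7 on it against 2.90 ± 0.24 (SD) on the other 5, Prl at 9.17 against 2.63, and the forebrain gene Nrgn at 9.11 against 3.98. The glycine transporter Slc6a5 stood at 3.61 against 7.69 and Hoxa5 at 2.73 against 6.38. Beside it, the cerebellar list (8 genes, none called under either adjustment) passed as higher in knockout brain with a median of 0.50 (adjusted p = 0.000512, adjusted p = 0.641 with an estimated correlation). The synaptic list (17 genes, none called under either adjustment) passed as lower with a median of -0.22 (adjusted p = 0.00569, adjusted p = 0.641 with an estimated correlation). Without that array both calls were lost (adjusted p = 0.461 and 0.67). Without it 56 genes were called, 28 up and 28 down, of which 39 were among the 71, and Ttll1, Nkain2, Tbc1d24, Srek1 and Ifitm3 lost their calls (adjusted p = 0.161, 0.295, 0.265, 0.075 and 0.0684). Nkain2, Tbc1d24 and Srek1 also lost them without knockout replicates 2 or 3 (0.0627 to 0.274 over the 3 genes), Ttll1 without knockout replicates 1 or 2 or wild-type replicate 2 (0.061 to 0.139), and Ifitm3 and Irgm1 without knockout replicate 3 (0.134 and 0.0843). The count was 34 without knockout replicate 3, 158 without wild-type replicate 1 and 114 without wild-type replicate 2. It was 25 for brain fitted alone, with 10 of the 16 named genes kept, 190 with array weights, 118 with every probe set and 46 with either filter on dim genes.

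In heart Asns, asparagine synthetase, rose by 4.19 ± 0.45 on the log2 scale (SE, n = 3 per genotype), Aldh1l2, a mitochondrial folate enzyme, by 2.93 ± 0.31 and Phgdh, the first enzyme of serine synthesis, by 2.71 ± 0.30. The antiviral genes Usp18, Ifit1 and Ifit3 rose by 4.06 ± 0.19, 3.86 ± 0.19 and 3.14 ± 0.23, Ifi27 by 2.69 ± 0.12 and Irf7, a regulator of interferon genes, by 2.62 ± 0.20. The immunoglobulin segment Igkj1 rose by 3.31 ± 0.77 and the B-cell chemokine Cxcl13 by 2.82 ± 0.50. With wild-type means under 4, the rises of Asns, Usp18, Igkj1 and Cxcl13 are read as lower bounds. Knockout SDs were 1.54 for Igkj1 and 1.9 for Cxcl13, so their pooled SEs understate the spread of the knockout heart arrays. The wild-type SD of Aldh1l2 was 1.05, so its pooled SE understates the wild-type spread. Besides Clpp, the chemokine Cxcl14 fell by 1.91 ± 0.32, the prolyl hydroxylase Egln3 by 1.82 ± 0.31, the sodium channel subunit Scn4b by 1.67 ± 0.24 and the lectin-like receptor Klra9 by 1.60 ± 0.27. Igsf1, Rpl3l, a ribosomal protein of striated muscle, Ky, Gpr22 and Smco1 changed by between -1.43 and -1.26. Rpl3l stood at 10.0 on knockout replicate 1 and at a mean of 8.68 on the other 2 knockout arrays, against a wild-type mean of 10.5. Its fall was thus larger on the 2 arrays with atrial and fat transcripts. Gpr22 and Smco1 also varied more among knockout arrays (SD 0.70 and 0.67) than among wild-type arrays (0.16 and 0.11). In all 372 genes were called, 189 up and 183 down, with 107 rises and 41 falls of at least 1. After a second quantile normalization 214 rose and 151 fell, and after median centring 180 rose and 238 fell. The eligible genes also held 1 rise and 3 falls with clone names.

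Of 29 integrated stress response targets in heart 13 rose, 19 adjusted over the list alone, and none fell (median 0.90; adjusted p = 1.13e-28, and adjusted p = 0.00227 with an estimated correlation). After Asns, Aldh1l2 and Phgdh came the glutathione-degrading Chac1 at 2.58 ± 0.53, whose call was lost without knockout replicate 3 or wild-type replicate 2 (adjusted p = 0.0637 and 0.0513). The list's median stood at 0.55, 0.91 and 1.37 above the wild-type mean on knockout replicates 1, 2 and 3, so it was higher on the 2 arrays with atrial and fat transcripts. Of 36 type I interferon-stimulated genes 19 rose, 30 adjusted over the list alone, and none fell (median 0.81; adjusted p = 1.82e-56, and adjusted p = 7.76e-06 with an estimated correlation). Of 21 interferon-gamma and GTPase genes 10 rose, 16 adjusted over the list alone (median 0.95; adjusted p = 1.42e-20, and adjusted p = 0.00776 with an estimated correlation), led by the GTPases Igtp, Irgm2 and Irgm1 at 2.16 ± 0.32, 1.97 ± 0.31 and 1.68 ± 0.23. Igtp stood at 9.68 on knockout replicate 1 against a mean of 8.19 on the other 2 knockout arrays, so its rise was larger there. The lists of mitochondrial DNA maintenance and expression factors (32 genes) and of oxidative phosphorylation (78 genes) passed as lower with no member called under either adjustment. Their medians were -0.24 and -0.14 (adjusted p = 4.04e-06 and 1.65e-06, but adjusted p = 0.0821 and 0.641 with an estimated correlation). On knockout replicates 1, 2 and 3 the medians were -0.11, -0.32 and -0.27 for the first list and -0.05, -0.16 and -0.18 for the second, lower on the 2 arrays with atrial and fat transcripts. Of 21 markers on the list of macrophages and microglia 2 rose, 8 adjusted over the list alone (median 0.43; adjusted p = 9e-07, but adjusted p = 0.492 with an estimated correlation). Tmem119 rose by 0.92 ± 0.17 and Fcer1g by 0.84 ± 0.21, the latter lost without knockout replicates 2 or 3 or wild-type replicates 1 or 2 (adjusted p between 0.0642 and 0.157). The median of the macrophage and microglial list was 0.18, 0.47 and 0.91 on knockout replicates 1, 2 and 3. That of the fibroblast list was -0.25, 0.82 and 0.77, so both were higher on the 2 arrays with atrial and fat transcripts.

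The 3 knockout heart arrays differed from each other. The atrial light chains Myl7 and Myl4 stood at 3.59 and 3.34 on knockout replicate 1 and at means of 12.7 and 12.5 on the other 2 knockout arrays, with wild-type means of 4.72 and 5.53. The fat genes Adipoq and Ucp1 stood at 2.57 and 2.78 against 8.65 and 7.48, and the liver gene Alb at 8.33 against 5.97. The atrial list (7 genes, 1 called and 4 adjusted over the list alone) passed as higher with a median of 1.24 (adjusted p = 0.00462, adjusted p = 0.641 with an estimated correlation), and lost its call without knockout replicate 2 or 3 (adjusted p = 0.0639 and 0.154). The hepatocyte list (15 genes, none called and 2 adjusted over the list alone) passed as higher with a median of 0.35 (adjusted p = 0.000149, adjusted p = 0.292 with an estimated correlation), and lost its call without knockout replicate 1 (adjusted p = 0.159). Without knockout replicate 1 the count of heart genes was 789, 481 up and 308 down, of which 329 were among the 372. It was 198 without knockout replicate 2, 206 without knockout replicate 3, 246 without wild-type replicate 1 and 224 without wild-type replicate 2. Igkj1 lost its call without knockout replicate 3 or any wild-type array (adjusted p between 0.0548 and 0.145), Igsf1 without knockout replicate 3 or wild-type replicate 2 (0.146 and 0.148), and Rpl3l without knockout replicate 2 or 3 (0.0642 and 0.0728). Fitted alone, heart gave 83 genes, 10 of the 20 named among them, and array weights gave 1146.

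**Figure D3:**
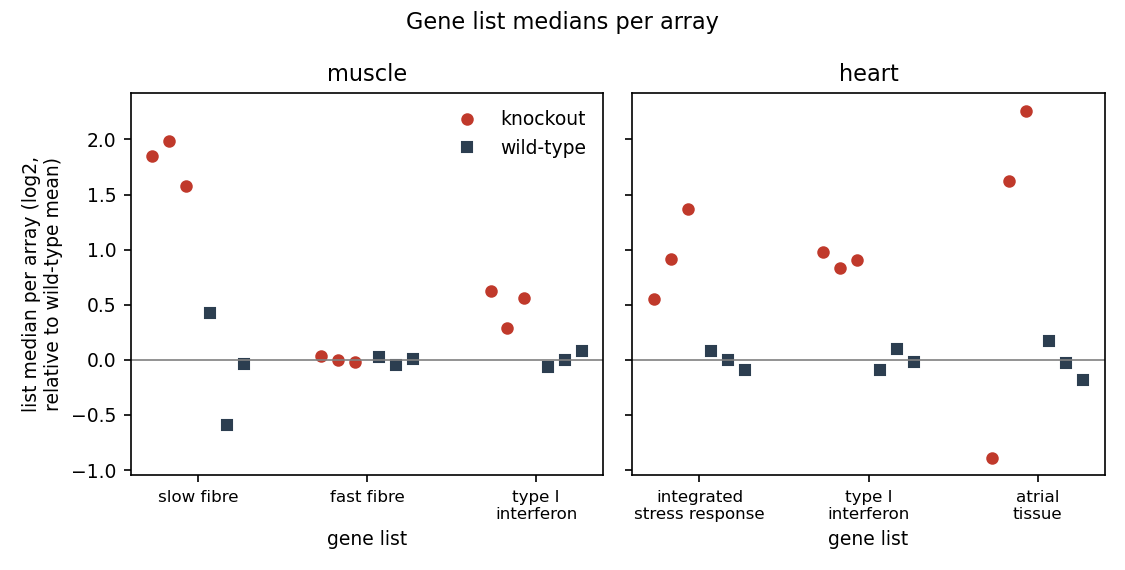
Median of each gene list on each array (log2, relative to the mean of the 3 wild-type arrays of the tissue) in muscle and heart, with knockout arrays as circles and wild-type arrays as squares. The slow fibre list stands between 1.58 and 1.99 on the muscle knockout arrays, the stress response list between 0.55 and 1.37 on the heart knockout arrays, and the atrial list at -0.89 on heart knockout replicate 1 against 1.62 and 2.26 on the other 2.

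On average over the 5 tissues, 12 of the 15 largest rises were genes of the 2 interferon lists. Usp18, which removes the ubiquitin-like ISG15, rose by 2.23 ± 0.09 on the log2 scale (SE, 15 arrays per genotype, from as few as 3 animals if each gave all 5 tissues), the antiviral Ifit1 and Ifit3 by 2.16 ± 0.08 and 1.86 ± 0.10, Rtp4 by 1.59 ± 0.09, Ifi27 by 1.47 ± 0.05, the antiviral Rsad2 by 1.27 ± 0.07 and the regulator Irf7 by 1.26 ± 0.09. Tgtp1, Lgals3bp, Iigp1, Igtp and Gbp3 rose by between 1.30 and 1.54. Outside the lists were the antiviral Oas1g at 1.37, the guanylate-binding protein Gbp10 at 1.28 and the slow troponin Tnni1 at 1.45. Below Clpp at -4.77 ± 0.09, the falls were led by Ubqlnl at -1.24 ± 0.07, the translation factor Eif4e at -1.19 ± 0.08, the spermatid gene Theg at -1.18 ± 0.09 and the lipase gene Lipe at -1.16 ± 0.12. Pde1a, the nuclear proteins of sperm Tnp2 and Prm3, Fam187b, Usp50, Tmem225, Dcun1d1, Hdac11, Cdkn1c and Fam221b changed by between -1.11 and -0.96. With testis left out of the mean, all 15 falls but Clpp and the cell cycle inhibitor Cdkn1c lost their calls. In all 5748 genes (33.6%) were called, 2930 up and 2818 down, with 27 rises and 72 falls of at least 1, and 688 without testis. After a second quantile normalization 3252 rose and 2671 fell, and after median centring 2692 rose and 2954 fell. The eligible genes also held 17 rises and 25 falls with clone names. Of 36 type I interferon-stimulated genes 29 rose under either adjustment and none fell (median 0.70; adjusted p = 7.54e-22, and adjusted p = 0.0016 with an estimated correlation). Of 21 interferon-gamma and GTPase genes 18 rose under either adjustment (median 0.66; adjusted p = 8.92e-12, but adjusted p = 0.0788 with an estimated correlation). Of 29 integrated stress response targets 19 rose, 20 adjusted over the list alone (median 0.39; adjusted p = 1.64e-06, but adjusted p = 0.323 with an estimated correlation). The list's median was 0.90 in heart and 0.40 in testis, and 0.18 in brain, 0.05 in liver and 0.04 in muscle. In testis the median change was 0.69 over genes with a mean of at least 6. The 0.40 there lies under it and does not set the list apart.

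The tissues shared more rising genes than independent lists of their sizes would. Fisher's exact test takes genes as independent draws, which co-regulated genes are not, so its p values here are too small. The same animals may also have given several tissues. Deviations of same-numbered arrays correlated by a mean of 0.175 between muscle and heart, and by under 0.1 for every other pair of tissues. The value for other numbers, -0.0895 between muscle and heart, adds nothing, since deviations from a group mean cancel within the group. Usp18, Rsad2, Rtp4, Gbp3, Oasl2, Xaf1, Trim30a and Rnf213 rose in all 5 tissues, 8 genes in all, and 20 genes rose in at least 4 tissues, 15 of them on the 2 interferon lists of 57 genes. Of the 35 genes up in at least 3 tissues 22 were on these lists. Ifit1 changed by 0.12 ± 0.19 in testis, where it was not called, and rose by 1.83 in liver, 2.23 in muscle, 2.73 in brain and 3.86 in heart. Clpp was the 1 gene that fell in all 5, and 5 genes fell in at least 3. Brain and heart shared 24 rising genes where 0.442 were expected (adjusted p = 1.33e-36, Fisher's exact test), muscle and brain 18 (0.311 expected; adjusted p = 1.62e-27) and liver and heart 23 (1.72 expected; adjusted p = 3.53e-19). Testis shared 28 with brain (13.1 expected; adjusted p = 2.29e-06) and 65 with liver (51.2 expected; adjusted p = 0.0152), while 70 with heart and 47 with muscle did not pass (adjusted p = 0.136 and 0.295). Those 65 were among 156 liver rises, and of 257 liver falls 111 also rose in testis. Testis rises were thus about as frequent among liver falls, so that overlap shows no shared direction. Among falls 1 pair of tissues passed, liver and heart, with 10 shared genes (2.75 expected; adjusted p = 0.0046). Correlations of log2 changes over all genes between tissues reached at most 0.198.

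**Figure D4:**
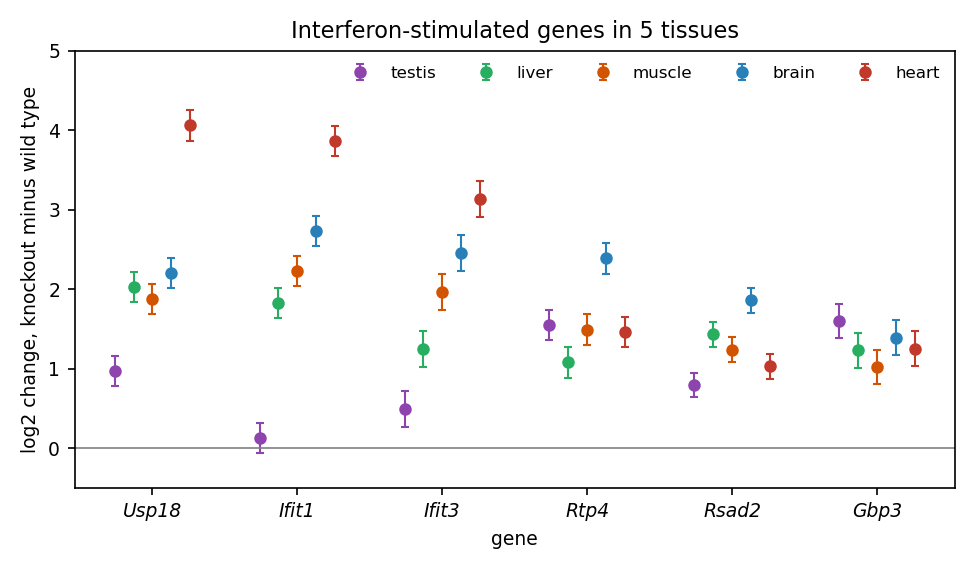
Log2 change (knockout minus wild type, ± SE, n = 3 arrays per genotype) of 6 interferon-stimulated genes in 5 tissues. Usp18 ranges from 0.97 in testis to 4.06 in heart, and Ifit1 from 0.12 in testis to 3.86 in heart.

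The knockout effect differed between tissues for 8941 of 17097 genes (52.3%) by the test of the 4 differences. The 5 genes with the smallest p were genes that fell in testis and stayed between -0.10 and 0.19 elsewhere. Bpifa3 fell by 5.12 ± 0.11 on the log2 scale (SE, n = 3 per genotype), and the spermatid actin-bundling Fscn3 fell by 5.40 ± 0.13. 4930406D18Rik, Tex46 and Cd109, a membrane protein that binds TGF-beta, changed by between -5.03 ± 0.12 and -4.26 ± 0.10, all 5 genes with adjusted p between 1.16e-17 and 2.01e-17. Among the other 4 tissues the effect differed for 244 genes. There Ifi27 changed by 0.92 in liver, 0.36 in muscle, 1.55 in brain and 2.69 in heart (adjusted p = 1.05e-06), and Serpina12 and the deiodinase Dio1 changed by -3.31 and -1.71 in liver. The change of Asns was 4.76 higher in heart than in the mean of the other 4 tissues (adjusted p = 1.44e-06). That is more than its rise of 4.19 in heart, so the mean change in the others was negative. For Usp18 in heart the difference was 2.29 (adjusted p = 9e-07), and both heart rises are read as lower bounds. For Tnnc1 in muscle the difference from the mean of the other 4 tissues was 4.69 (adjusted p = 1.03e-05). The integrated stress response list differed in heart by a median of 0.52 (adjusted p = 1.2e-08, but adjusted p = 0.334 with an estimated correlation) and the type I interferon list by 0.33 (adjusted p = 1.54e-07, but adjusted p = 0.197 with an estimated correlation).

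Genes near Clpp were compared with the rest of the genome because passenger alleles can surround a targeted locus. Of 131 genes within 10 Mb on chromosome 17, Treml4, a receptor of myeloid cells, rose by 0.56 ± 0.11 on the log2 scale in liver (adjusted p = 0.00542) and Plin3, a lipid droplet protein, rose by 0.81 ± 0.16 in muscle (adjusted p = 0.0109; SE, n = 3 per genotype). Clpp itself was left out, and over the 5 tissues and their mean the adjusted p of Fisher's exact test was at least 0.732. On average over tissues 43 of the 131 were called (32.8%), against 33.7% elsewhere (odds ratio 0.961, p = 0.926 in Fisher's exact test). In testis 78 were (59.5%, against 56.3% elsewhere; p = 0.48 in Fisher's exact test).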

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

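The tests of a slow muscle in the dissections, of another part of the brain, of swapped labels, of control probe sets against the other brain arrays, of a like rise of all other testis cells and of the difference among 4 tissues without testis were chosen after the result was seen.

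The knockout effect differed between tissues, by a test of that difference, for 8941 genes over all 5 tissues and for 244 genes without testis. In testis Bpifa3 changed by -5.12, 4930406D18Rik by -5.03, Fscn3 by -5.40, Cd109 by -4.26 and Tex46 by -4.50, against -0.10 to 0.19 in the other tissues. The Sertoli cell list differed from the other 4 tissues by a median of 1.79 in testis (adjusted p = 3.09e-06, and adjusted p = 0.0248 with an estimated correlation) and of -0.48 in muscle (adjusted p = 2.21e-05, and adjusted p = 0.0377 with an estimated correlation), the mean of the others including testis. The slow fibre list differed by 1.89 in muscle (adjusted p = 4.77e-10, and adjusted p = 0.0248 with an estimated correlation). Signal was also found in the 15588 probe sets with no gene name, of which 4935 were called in testis, 212 in liver, 123 in muscle, 96 in brain and 132 in heart.

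Splits of the arrays into other groups were counted for each result. In each tissue 10 splits of 6 arrays are too few for a share under 0.05; the real split gave 9605 genes in testis, 413 in liver, 263 in muscle, 71 in brain and 372 in heart, and the highest other split 56, 71, 36, 29 and 86, so 1 split in each reached the real value. For the difference between tissues the real split gave 8941 and the highest other 8202, with 1 of 100 as large, and for the mean over tissues 5748 and 6129, with 2 of 100 as large. The 8 other splits that kept the testis groups whole held the highest counts, and the 91 that mixed them gave at most 7 genes for the mean and 78 for the difference, which points to a structure of the samples set by testis. These counts follow whether the testis groups stay whole, and testis alone has too few splits, so they exclude chance for neither result.

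Slow fibre genes were higher in knockout muscle, with a median of 1.81 over 13 genes. Muscle from another part of the body stays open. The 18 limb and trunk position genes had a median absolute change of 0.165 in muscle and 0.146 in heart. They were taken whatever their signal, and genes near the floor cannot move. Nor could they tell apart muscles of the same limb. Heart RNA was argued against by the heart-restricted genes, whose mean change was 0.0328 ± 0.0672 (SE over genes). More of a slow muscle in the knockout dissections stays open, since fast fibre genes had a median change of 0.0134, as a mixture would give, and the labels do not name the muscle. A change of fibre type in the knockout may be the source too and cannot be told apart from it.

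Brain wild-type replicate 3 stood apart from the other 5 brain arrays. Degraded RNA, which raises the 3'-minus-5' difference, was argued against by an actin difference of 1.21, below the 1.24 to 1.32 of the other 5 brain arrays, with GAPDH at 0.33 within their 0.22 to 0.42. Swapped labels were argued against by its Clpp level of 7.79, where knockout arrays reached 3.99. Another part of the brain was left open by the Hox bound of 1 alone, set after the result was seen, while forebrain and cerebellar genes went with it. The median of 10 forebrain genes was 3.97 higher on this array, all 10 being higher. The Hox genes changed by a median of -0.98, just short of the bound, with none of 15 higher. Cerebellar genes went the same way with a median of -1.81 and none of 8 higher, while the striatal list hardly moved (median -0.02, 3 of 8 higher). In the brain comparison the 10 forebrain genes were all lower in knockout (median -1.23, none called), so region and genotype are mixed there. The other 5 brain arrays, of both genotypes, had the forebrain gene Nrgn at a mean of 3.98. Forebrain may thus be scarce in the brain comparison apart from this array. The genotype is shared with the other wild-type arrays, and no biological explanation was tested.

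In knockout testis 5608 genes were higher, among them all 17 Sertoli markers. A loss of spermatids that raises all other cells alike stays open for cells other than meiotic spermatocytes. Sertoli markers rose by 1.48 ± 0.26 more than endothelial, fibroblast and myoid markers (SE over genes). Those markers were taken whatever their signal in testis, and markers near the floor cannot rise. By their means, Leydig (1.40 ± 0.22), spermatogonial (1.04 ± 0.24) and macrophage markers (0.93 ± 0.31) rose nearer to Sertoli markers (1.66 ± 0.14). Meiotic spermatocyte markers did not rise as a set (-0.11 ± 0.38, with 10 of 22 up and 6 down). That argues against a like rise for those cells. A higher share of some cells other than spermatids, or a change within them, stays open as an untested biological explanation. Between-array normalization as the source also stays open. Scaling to equal medians gave 5594 higher genes but shifted the changes by only -0.00231, so that test moved nothing.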

How the results depend on the processing

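The fit without brain wild-type replicate 3 and muscle wild-type replicate 1 together and the comparison of 4 tissues without testis were chosen after the data were seen. Of 126 named gene results 67 kept direction and call under every alternative, 59 lost the call under at least 1 and 1 of them turned. Fitted alone, liver gave 31 genes, muscle 15, brain 25 and heart 83, with 17 genes in the overlap against 40. There 4 residual degrees of freedom replace 20, and the spread of the tissue's own arrays replaces the spread pooled over all groups. With a replicate block for same-numbered (paired) arrays muscle gave 137 and brain 41. Array weights gave 190 in brain, 1146 in heart and 68 in the overlap. The filter on the highest group mean, with 10207 genes tested, gave 46 in brain, and that on the overall mean, with 8548, gave 6393 in testis, 46 in brain, 3805 for the mean over tissues and 39 called list tests against 74. Every probe set tested on its own gave 435 in muscle and 118 in brain. Estimated correlation gave 13 list tests, the mean without testis 688 genes, an unadjusted p threshold for the overlap 90, and 4 tissues in place of 5 gave 244 genes that differed. Values that turned were Hamp2 (liver) at -0.0981 with specific probe sets, Abcc3 (mean) at 0.00361, Hsd17b3 (mean) at -0.0339 and Aif1 (mean) at 0.0885 without testis and Cyp2b9 (mean) at -0.00309 without liver, where the tissue with the change was removed. Leaving out 1 array at a time gave 8937 to 9292 genes in testis, 293 to 423 in liver, 125 to 277 in muscle, 34 to 158 in brain, 198 to 789 in heart, 5319 to 5989 for the mean, 8180 to 9180 for the difference between tissues, 32 to 44 in the overlap, 64 to 86 list tests and an odds ratio near Clpp of 0.897 to 1.15. The counts beyond 1.5 times were 125, 165, 142, 156 and 141 in muscle without knockout replicates 1, 2 and 3 and wild-type replicates 1 and 3, 34, 158 and 114 in brain without knockout replicate 3 and wild-type replicates 1 and 2, and 789, 198, 206, 246 and 224 in heart without knockout replicates 1, 2 and 3 and wild-type replicates 1 and 2. Without brain wild-type replicate 3 and muscle wild-type replicate 1 together, brain gave 54 and muscle 196. Except for the fits of single tissues, the tissues left out of the mean and the filters, whose construction shows it, the cause was not tested. Fits of single tissues gave no value for the mean or the difference between tissues. Signal reached a mean of at least 6 for 5168 of 17097 genes, and how calling depends on signal level was not tested.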

Other observations

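The lists of male-biased and female-biased liver genes, the atrial, fat and epididymal genes named here and the left-out arrays were looked at after the result was seen.

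Sex-biased liver genes were also looked at by direction. Of 8 male-biased genes 6 fell and all 8 were lower, with a median of -1.59 and a mean of -1.61 ± 0.27 (SE over genes), among them Elovl3, an elongase of fatty acids, at -2.10. Of 5 female-biased genes 2 rose, Cyp2b9 and Cyp2b13, and 4 were higher, with a median of 0.61. Their median was 1.77 on knockout replicate 1 but 0.23 and 0.09 on knockout replicates 2 and 3, against -0.45 to 0.08 on the wild-type arrays, so the median rested on 1 array, that with the highest actin and GAPDH control differences of all 30.

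The list of mitochondrial proteases and chaperones, the group to which ClpP belongs, had no called member among 20 in liver, muscle, brain or heart with limma, under either adjustment. Its medians were -0.02, 0.00118, -0.04 and -0.13 (adjusted p = 0.872, 0.711, 0.514 and 0.106). In testis 11 rose and 3 fell, 11 and 4 adjusted over the list alone (median 0.49; adjusted p = 0.384). There the matrix protease Lonp1 rose by 1.81 ± 0.12 on the log2 scale (SE, n = 3 per genotype) and the processing peptidase Mipep fell by 2.19 ± 0.14.

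In heart, atrial and fat genes rested on 2 of the 3 knockout arrays. Without knockout replicate 1 the atrial light chain Myl7 changed by 7.99 (adjusted p = 1.01e-08) in place of 4.94 ± 1.36 (adjusted p = 0.0552), and the thermogenic Ucp1 by 4.64 (adjusted p = 1.64e-13) in place of 3.07 ± 0.66 (adjusted p = 0.01). The wild-type mean of Ucp1 was 2.84, below the array medians, so its changes are read as lower bounds. In testis the epididymal lipocalin Lcn5 changed by -3.21 with all arrays and by -0.25 without wild-type replicate 3, and Lcn8 by -2.70 and -0.11.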
